A study of Mus musculus with 3 samples.

How the data were processed

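Nrf2 binding was measured by ChIP-seq in Keap1-deficient mouse embryonic fibroblasts. Per the labels' protocols, cells were crosslinked with formaldehyde and sonicated, the chromatin was precipitated with either of 2 rabbit antibodies to Nrf2, and the DNA was sequenced beside a control library. The labels give 1 library per antibody and 1 control. Groups were taken from the sample titles, and with 1 library per group no test between groups was possible.

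The deposited file is a list of 1256 regions with 5 columns: chromosome, start, end, highest position and height at that position. The column names and values, per the file headers, give the height as a signal: a height that is never negative and often fractional, with whole-number values in 58 regions (4.62%, exact to the decimals deposited). The unit of the height, its normalization, the aligner, the peak caller, its thresholds and how the antibody libraries and the control were combined are not given in the sources used here. The lowest height deposited was 5. The genome build was mm9, per the submitters' processing notes. A table of mouse genes from the later assembly GRCm38 was used only for the number of protein-coding genes per chromosome. On 5 chromosomes (1, 5, 7, 8 and 19) the list reached beyond the last gene of that table, so positions of the list and the table were not combined. Positions are printed as deposited, and whether they count from 0 or 1 is not stated. No column belonged to a single sample, and no row was a duplicate. Depth per sample is unknown, and intervals cover counting error of regions only.

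From the list, widths, gaps, heights and counts per chromosome were computed. The length of a chromosome was taken as the end of its last region, since no mm9 lengths were used here. This understates the length of chromosomes with few regions and so raises their density. Regions per chromosome were compared with length by a chi-square statistic against 100000 simulated tables and by two-sided exact binomial tests, with Benjamini-Hochberg adjustment over 20 chromosomes and a threshold of 0.05. Intervals are exact Clopper-Pearson intervals at 95%. Y, with a single region, was left out. X was kept in the expectation. Loci are regions joined across gaps of at most 100 kb. Dense stretches are chains of at least 5 regions with gaps of at most 20 kb, compared with 1000 random placements (100 for the count of regions within 20 kb). Correlations have two-sided permutation p-values from 100000 permutations, and the comparison of heights between autosomes used 10000.

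Before the data were examined, rules of naming were fixed. The first named the genes of the 10 regions with the largest enrichment value or score. Further rules named genes of fixed gene lists with a region, the genes with the most regions, and the regions differing most between the antibodies. These further rules need genes or values per library and were not followed. For the first rule, height was taken for the enrichment value once the file was seen, and regions are named in place of genes. The regions of chromosomes X and Y and the dense stretches were chosen after their values were seen. Also fixed before the data were examined were 10 gene lists with 285 genes. They covered glutathione and thioredoxin, quinone and xenobiotic metabolism, heme and iron, NADPH supply, Nrf2 regulators, proteasome, cell survival, cell cycle, fibroblast and other-lineage genes. The lists were not tested, because linking regions to genes needs an mm9 annotation. For the same reason distance to start sites and the antioxidant response element were not analysed here. Enrichment over the control and agreement of the antibodies need values per library, and in their place the distribution of heights is described.

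The tests were tested on simulated data. With 20 chromosomes and no departure, 0.475% were called. These draws placed regions independently, so the rate of false calls with crowded regions was not simulated. Chromosome 1 simulated at 2 times its share and X at a low share were called in 100% of draws. All planted stretches of 10 regions among 1256 were found (100%), and random placements gave 0 stretches. Over 19 autosomes, 3% of unrelated pairs passed an unadjusted 0.05 and 98% of pairs simulated with a strong correlation did. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternatives were the 628 tallest regions, merging within 1 kb, loci, heights of 9 or more or under 9, leaving out dense stretches, gene numbers as the expectation, other definitions of a stretch, and leaving out the tallest 1% of regions.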

Results

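Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where Nrf2 binds in the genome of mouse embryonic fibroblasts. Nrf2 is a basic leucine zipper transcription factor that, with small Maf proteins, binds antioxidant response elements near genes of detoxification and redox defence. The cells lacked Keap1, the adaptor that normally delivers Nrf2 to a ubiquitin ligase for degradation, so that Nrf2 was permanently active. The series comprised 3 libraries: 1 made with a monoclonal antibody to the C-terminal part of Nrf2, 1 made with a polyclonal antibody to the N-terminal part, and 1 control. There was 1 library of each kind and therefore no replicate. The sources differ on the control, which the sample label ties to a rabbit IgG antibody and the design text describes as input DNA.

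The deposited result was a single list of regions for the whole series, with no value for any single library. The depth of the libraries is unknown, and enrichment over the control and the difference between the 2 antibodies were not analysed here. The height of a region is the authors' own value, and it is compared below only between regions of this list. Regions are given by their mm9 positions as deposited, and no gene is named because no mm9 annotation was used here.

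The list held 1256 regions from the Nrf2 ChIP-seq, spread over all 19 autosomes, X and Y. Which of them are sites bound by Nrf2 was not tested. The regions were short, with a median width of 345 bp and a mean of 351 ± 89.6 bp (SD over regions), and together they covered 441 kb. Widths ran from 20 to 1126 bp. In regions that touched no other region, the highest position lay close to the middle, at a median distance of 4.77% of the width. Most regions stood alone, and the median gap from one region to the next was 815 kb. A smaller set touched a neighbour, and 42 regions began at the position where the previous one ended. Joining regions within 1 kb of each other gave 1169 loci, and joining them within 100 kb gave 968.

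Region heights ranged from 5 to 122 with a median of 10.1 (95% interval of the median over regions, 9.91 to 10.3). A long tail of tall regions was present, with 107 regions (8.52%) above 20 and 40 regions (3.18%) above 30. Taller regions were only slightly wider. Across the 1256 regions, Pearson's r between width and log2 height was 0.12 (permutation p = 1.0e-05, the smallest that the permutations can give, adjusted p = 6.0e-05). Spearman's rho was 0.081 (two-sided permutation p = 0.00399, adjusted p = 0.00598 over the 6 coefficients of 3 relations tested). Regions are not independent replicates, and without the 121 regions in dense stretches described below, rho was 0.0491 and no longer passed the threshold.

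The distribution of heights started high at 5, the lowest height in the list, and stepped up again at 9. Counts fell from 191 regions at heights of 5 to 6 to 85 at 6 to 7, 48 at 7 to 8 and 46 at 8 to 9. They then rose to 247 regions at 9 to 10 and fell again to 137 at 10 to 11. In all, 370 regions (29.5%, exact 95% interval 26.9 to 32.1%) were lower than 9 and 886 regions reached 9 or more. The lower regions had a median width of 328.5 bp and the taller ones of 350 bp.

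**Figure D1:**
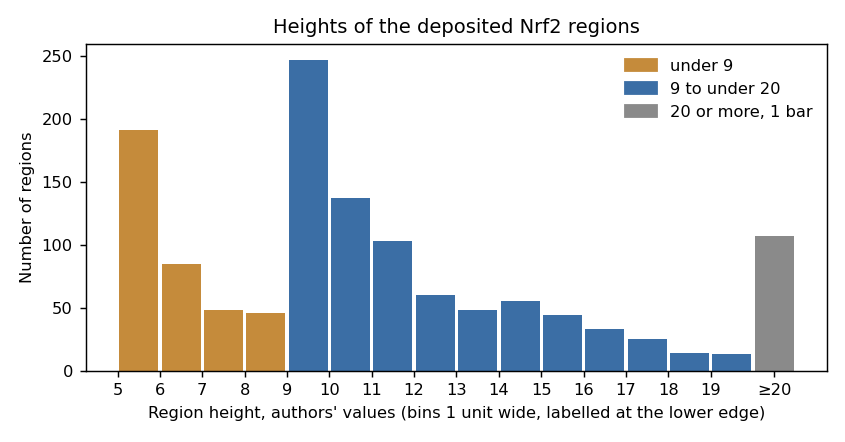
Number of regions (vertical axis) by region height in the authors' values (horizontal axis, bins 1 unit wide), with all regions of height 20 or more in the grey bar. Orange bars are heights under 9 and blue bars heights of 9 to 20; 46 regions lie between 8 and 9 and 247 between 9 and 10.

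The 10 tallest regions lay on 7 chromosomes. The tallest region of the list was on chromosome 2 from 98505263 to 98505490, with a height of 122.128. Chromosome 15 held a neighbouring pair, the region from 74916512 to 74917578 with a height of 87.181 and the region from 74915851 to 74916345 with a height of 54.502. The region on chromosome 12 from 75905342 to 75905601 reached 79.477, and the region on chromosome 17 from 46207075 to 46207425 reached 67.583. A second region of chromosome 17, from 39984258 to 39985319, had a height of 48.441. On chromosome 9, the region from 3019143 to 3019203 had a height of 55.959 and the region from 3031732 to 3031924 a height of 53.171. The remaining pair were on chromosome 14 from 75133233 to 75133542, with a height of 47.388, and on chromosome 4 from 3016984 to 3017318, with a height of 47.376. Of these 10 regions, 4 were in dense stretches of regions: both on chromosome 9, the one on chromosome 4 and the second one on chromosome 17. None was on chromosome 1, where the tallest region had a height of 35.6. Whether heights were corrected for the control is not given. Piling up of reads at repeated sequence was not tested for these regions one by one. Distances of the highest position from the middle, weighed below, were tested for the dense stretches as a set. Among regions touching no other, their median was 38.0% of the width in the chromosome 9 stretch. It was 20.7% in the chromosome 17 stretch (2 regions) and 17.2% in the chromosome 4 stretch, against 4.58% outside dense stretches. The second region of chromosome 17 touched another and was not among those measured. Height alone therefore does not show that these 10 regions are the strongest Nrf2 sites.

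The listed regions were unevenly spread over the chromosomes. Chromosomes 10, 15, 19 and 1 carried 1.8 to 2.0 times the number of regions that their length predicted, chromosome 7 about 0.47 times and chromosome X 0.0747 times. The departure from length was beyond counting error (chi-square 349 on 19 degrees of freedom, p = 1.0e-05 from 100000 simulated tables, the smallest that these can give). Of 20 chromosomes tested with two-sided exact binomial tests and Benjamini-Hochberg adjustment, 6 carried more regions than expected and 7 fewer. These tests treat regions as independent, which neighbouring regions are not. The expectation included X, whose shortage (6 regions against 80.3 expected) raises the ratio of every autosome somewhat and lessens the deficits. With regions within 100 kb counted once, 5 chromosomes carried more loci than expected and 6 fewer.

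Chromosome 10 held 122 regions against 62.6 expected (observed over expected 1.95, exact 95% interval 1.63 to 2.31, adjusted exact p = 3.6e-11), and 2.18 times the loci predicted. Chromosome 15 held 96 regions against 49.9 expected (1.92, interval 1.57 to 2.33, adjusted exact p = 1.5e-08), and 2.16 times the loci predicted. Chromosome 19 held 54 regions against 29.6 expected (1.82, interval 1.38 to 2.36). Chromosome 1 had more regions than any other chromosome, 172 against 95.1 expected (1.81, interval 1.56 to 2.08, adjusted exact p = 9.7e-13). Of these, 56 lay in dense stretches, and its ratio was 1.35 when loci were counted (adjusted exact p = 0.00627). Chromosomes 17 and 16 had ratios of 1.47 and 1.49, and the excess of chromosome 16 did not pass the test when loci were counted (1.30, adjusted exact p = 0.115). On chromosome 17, regions of height 9 or more were 1.77 times the expected number and regions under 9 were 0.758 times. The regions under 9 numbered only 10, and their ratio did not pass the test. Among the 628 tallest regions, the excesses of chromosomes 10 (1.28) and 16 (1.40) did not pass the test. Nor did that of chromosome 16 among regions of height 9 or more (1.385). With the number of protein-coding genes per chromosome in place of length, the excesses of chromosomes 17 (1.07) and 19 (1.32) did not pass.

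Chromosomes 4, 6, 7, 9, 12 and 18 held fewer regions than their lengths predicted. Chromosome 7 held 34 regions against 72.1 expected (0.472, interval 0.328 to 0.655), and chromosome 18 held 21 against 39.8 (0.528, interval 0.328 to 0.804). The deficit of chromosome 12 (33 regions against 56.4) did not pass the test when loci were counted (adjusted exact p = 0.0596). Among the 628 tallest regions, the deficits of chromosomes 4, 6, 9 and 18 did not pass, with ratios of 0.651 to 0.841. Among regions of height 9 or more, the deficits of chromosomes 9 (0.739) and 18 (0.677) did not pass. Among regions under 9, those of chromosomes 6 (0.578) and 12 (0.603) did not. With gene numbers in place of length, those of chromosomes 12 (0.838) and 18 (0.708) did not pass. Chromosomes 2, 3, 5, 8, 11, 13 and 14 did not pass the test, with ratios of 0.805 to 1.10.

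**Figure D2:**
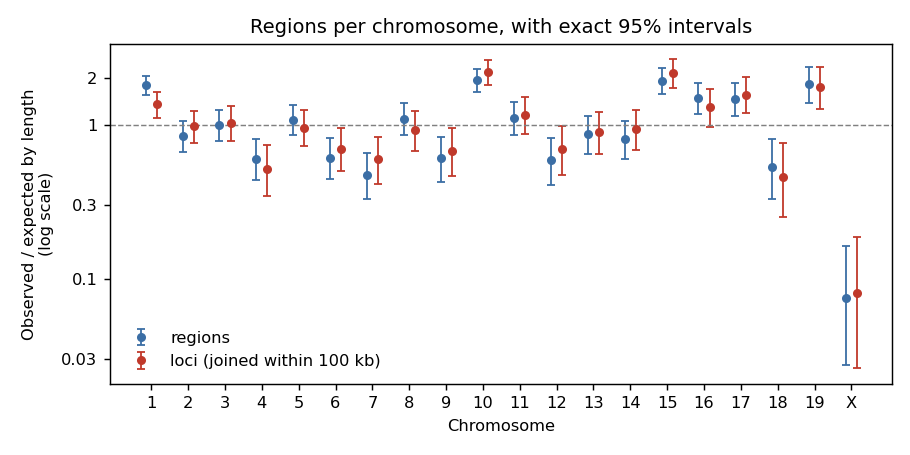
Number of regions (blue) and of loci, that is regions joined within 100 kb (red), on each chromosome divided by the number expected from its length, on a log scale; bars are exact 95% intervals of counting error. Chromosomes 10 and 15 lie near 2 by either count, and chromosome X lies below 0.1.

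No relation between the density of loci and the density of genes was detected, but simulations covered only a correlation of 0.8, so a weaker one is not excluded. Over the 19 autosomes, Pearson's r between loci per Mb and protein-coding genes per Mb was 0.0514 (permutation p = 0.836) and Spearman's rho was 0.0877 (permutation p = 0.72, adjusted p = 0.836). Without chromosomes 7 and 11, the 2 farthest from the median gene density, r was 0.244. Regions under a height of 9 and taller regions tended to be dense on the same chromosomes, though chromosome 17 had an excess of taller regions only (above). Counted as loci by their tallest region, their densities per Mb correlated over the 19 autosomes with r = 0.76 (permutation p = 3.0e-05, adjusted p = 9.0e-05) and rho = 0.79 (permutation p = 9.0e-05, adjusted p = 1.8e-04). Without chromosomes 10 and 19, r was 0.70. The share of regions under 9 ran from 9.52% on chromosome 18 to 39.6% on chromosome 15, and was 39.3% on chromosome 10. These shares differed between autosomes (permutation p = 0.012), but not past the threshold without the regions in dense stretches (permutation p = 0.083).

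Chromosome X had 6 regions against 80.3 expected from its length (0.0747, exact 95% interval 0.0275 to 0.162, adjusted exact p = 1.8e-26). All 19 autosomes had higher ratios, from 0.472 to 1.95. Of the 6 regions, 4 had heights of 5 to 5.307. The other two were the region from 71670561 to 71670881, with a height of 15.353, and the region from 109484622 to 109484842, with a height of 12.813. Chromosome Y had 1 region, from 2689159 to 2689398, with a height of 6, and was left out of the tests.

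Some regions crowded into short stretches. Defined as at least 5 regions with gaps of at most 20 kb, 12 dense stretches held 121 regions (9.63%) within 342 kb on 8 chromosomes. In 1000 random placements of the same regions on their own chromosomes, no placement gave a dense stretch (permutation p = 0.001, the smallest that the placements can give). Of all regions, 192 lay within 20 kb of the previous one, against a mean of 16.4 and a maximum of 28 in 100 random placements. That count takes in most regions of the dense stretches and is not separate evidence. With touching regions counted as 1, there were 7 dense stretches by the same definition. Of the 121 regions in dense stretches, 42 (34.7%) touched another region, against 33 (2.91%) of the 1135 other regions, a difference that the definition by small gaps itself favours and that was not tested. The stretches and their definition were chosen after the positions were seen.

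The stretch with the most regions was on chromosome 1 from 90108164 to 90200823, where 38 regions lay within 92.7 kb with a median height of 9.73 and a maximum of 15.7. Another 3 stretches of chromosome 1 lay within a few Mb of it: from 85252163 to 85289436 with 7 regions, from 87488150 to 87493286 with 6 and from 85076225 to 85089478 with 5. Stretches of 13 regions lay on chromosome 8 from 19922538 to 19946759 and on chromosome 16 from 3235944 to 3272167. The stretch on chromosome 17 from 39979893 to 39996380 held 8 regions, all tall, with heights of 20.9 to 48.4. Chromosome 5 had a stretch of 6 regions from 15179295 to 15207858 and one of 5 regions from 14933628 to 14978355. Stretches at the beginning of the sequence of chromosomes 4, 9 and 18 held 8, 5 and 7 regions. The 5 regions on chromosome 9, from 3005683 to 3031924, had a median height of 33.2. The median height over all dense stretches was 10.6, and that of the other regions was 10.0.

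**Figure D3:**
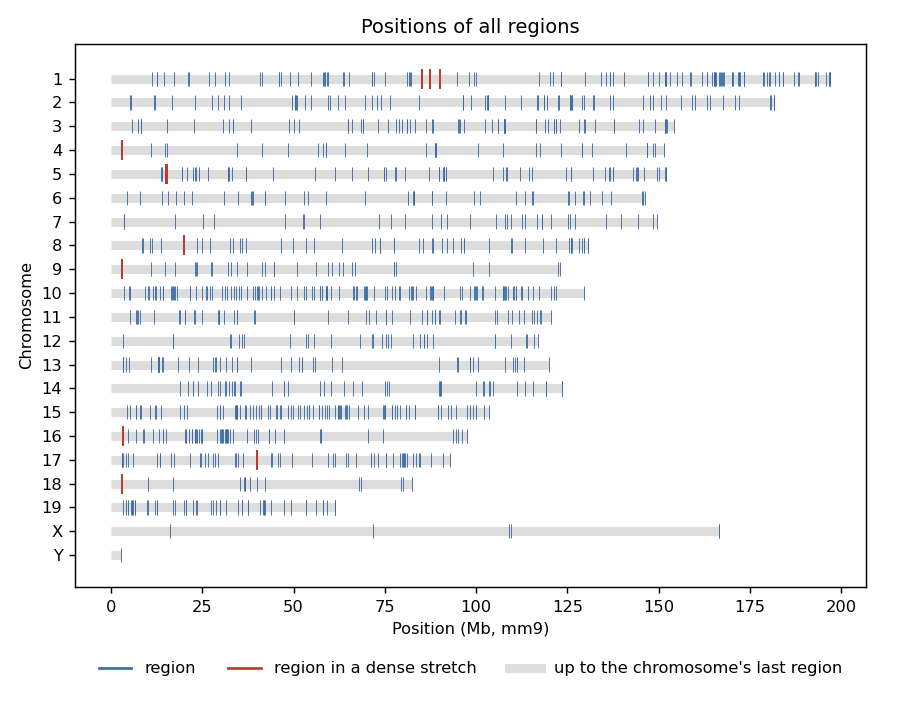
Position of each region along the chromosomes in Mb of mm9 (horizontal axis); blue ticks are single regions, red ticks are the 121 regions in dense stretches, and grey bars end at the last region of each chromosome. Ticks are close together along the whole of chromosome 10 and most of chromosome 15, and nearly absent from X.

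**Figure D4:**
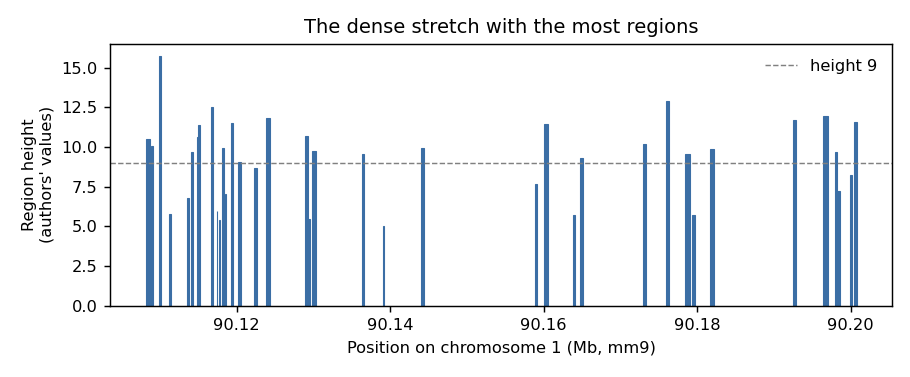
Height of each region in the authors' values (vertical axis) by position on chromosome 1 in Mb of mm9 (horizontal axis) in the dense stretch with the most regions, with each bar as wide as its region; the dashed line marks a height of 9. The 38 regions range in height from 5 to 15.7.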

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

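Settings other than the 628 tallest regions, merging within 1 kb, removal of duplicates, the mean and leaving out the tallest 1% were chosen after the data were seen. The list shrank from 1256 to 628 when only the tallest were kept, by construction, and kept between 886 and 1256 under the other settings. Of 13 chromosomes departing from length, 7 did among the tallest 628, and 10 to 13 in the other settings by length. With gene numbers as the expectation, 9 of the 13 did, along with chromosomes 2, 3 and 11. Among the tallest 628, fewer regions were tested, and some ratios were also nearer to 1. Over the 13 chromosomes and 6 settings, 60 ratios stayed on the same side of 1 and of the threshold, and 17 kept only their direction. The remaining ratio, that of chromosome 17, fell to 0.758 among regions under a height of 9. It rested on 10 regions and did not pass the test, and the cause was not tested. X stayed below expectation throughout (0.0353 to 0.169). The median height of 10.1 became 13.6 among the tallest 628, by construction, and the mean was 11.9. Spearman's rho of width with height was 0.0491 without the dense stretches, and the cause was not tested. The 12 dense stretches became 3 with at least 10 regions, 7 with touching regions counted as 1, and 12 or 13 with gaps of 10 or 50 kb. The first 2 settings can only lower or keep the number, but the size of the fall was not fixed. Some stretches thus reached 5 regions only through regions that touch. Pseudocounts, overlap limits between antibodies, distances to start sites, gene lists and their backgrounds and the motif alternatives were not run, since the list holds no values per library and no mm9 genome or annotation was used. Depth is unknown, so whether a sparse chromosome lacks binding or lacks reads cannot be read from the list. Nor can it be read whether a dense chromosome has more binding or more reads.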

Other observations

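The excess of loci on chromosomes 10 and 15 was present in each part of their length, though the parts were not tested one by one. Counted as regions, it was larger under a height of 9 (2.609 and 2.588 times expected) than at 9 or more (1.675 and 1.645). That difference was not tested for these chromosomes by themselves. Over all autosomes, shares of regions under 9 differed (permutation p = 0.012), but not past the threshold without dense stretches (permutation p = 0.083). With each chromosome divided into 4 equal parts up to its last region, chromosome 10 held 26, 28, 26 and 25 loci, against 12.8 expected per part from the autosomal mean of 0.395 loci per Mb. Chromosome 15 held 13, 26, 26 and 18 loci against 10.2 expected, and chromosome 19 held 11, 12, 9 and 8 against 6.06. These were the 3 autosomes on which each part exceeded its expectation. Chromosome 1 held 46 of its 99 loci in the last part, against 19.5 expected, and chromosome 16 held 18 and 20 loci in its first parts and 3 and 6 in its last, against 9.63 expected.

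Some of the tallest regions lay near the beginning of the mm9 sequence. Before position 3.1 Mb, 8 regions lay on chromosome 4, 5 on chromosome 9, 7 on chromosome 18 and 4 on chromosome 17. Those on chromosomes 4, 9 and 18 are the dense stretches already described. Of the 10 tallest regions of the list, 3 were among them. Their median height, with the Y region, was 11.9, against 10.0 for all other regions.

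In the 3 patterns weighed below, the tests of random placement and of a single X were chosen after the result was seen. So was the ratio set beside the joined lists. The list has no groups to compare, so no difference between groups was tested as an explanation.

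The first pattern is the crowding of regions into 12 dense stretches. Random placement on the chromosomes gave none in 1000 draws (permutation p = 0.001) and is argued against. Repeated or copied sequence that piles up reads was taken to give irregular regions. Among regions touching no other, summits lay a median of 10.8% of the width from the middle in dense stretches and 4.58% elsewhere, and the median was larger than elsewhere in 12 of 12 stretches (exact two-sided sign test p = 4.9e-04). The sign test treats stretches as independent, although 4 of them lie within a few Mb on chromosome 1. Some of the medians rest on only 2 regions, and the lowest was 5.49%. The larger offsets go with piled-up reads at repeated sequence, but repeats themselves were not examined. The offset is a percent of the width, and most stretches had a median width under the 345 bp of the whole list, the lowest being 212 bp. Whether narrower regions alone bring larger offsets was not tested. Many true sites close together, whose reads overlap, may blur summits too and stay open.

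The second pattern is the step in region heights at 9. Heights of 9 to 9.5 were 4.03 times as frequent as heights of 8.5 to 9 (117 against 29 regions, exact 95% interval of the ratio 2.67 to 6.29). A candidate explanation is that 2 lists with different minimum heights, 5 and 9, were joined into 1. The ratio restates the step that prompted this explanation and cannot test it. The dense stretches did not bring the step, since the ratio was 4.40 without them (interval 2.83 to 7.09). Whether lists were joined, which libraries they came from, and whether a height of 9 would mean the same in each stays open. Heights below and above 9 may therefore not be on one scale.

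The third pattern is the scarcity of regions on X. Fewer genes on X are argued against: relative to its share of protein-coding genes, X had 0.107 times the expected regions (exact 95% interval 0.0393 to 0.232), below the lowest autosome at 0.289. A single copy of X, with heights 0.5 times those on autosomes, is argued against if the list had 1 minimum height of 5: autosomal regions of height 10 or more then predict 43.6 regions on X, and 18.9 from the sparsest autosome (chromosome 7), against 6 listed (exact Poisson interval 2.20 to 13.1). If part of the list had a minimum of 9, as the step in heights allows, that prediction is too high, and a single copy cannot be told apart from other causes. Autosomal regions of height 18 or more then predict 9.16 regions of height 9 or more, against 2 listed (exact Poisson interval 0.242 to 7.22). That interval lies below the prediction, and 12 of 19 autosomes predicted more than its upper bound, but single autosomes ran from 2.23 (chromosome 7) to 34.0 (chromosome 17), a spread that the bound set for this test had ignored.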
